A study of Homo sapiens with 3 samples.

How the data were processed

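RNA sequencing of 3 libraries of cells labelled KG1a was analysed: 1 control library and 2 TRAF7 knockdown libraries. Per the labels' protocols, cells were infected with lentivirus carrying a control or a TRAF7 hairpin, and libraries were made from total RNA. All 3 carry the same batch label. The labels do not state whether the 2 knockdown libraries come from separate cultures or hairpins, so p-values measure the spread between these samples, which may be technical.

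The authors deposited FPKM values (read counts scaled by exon length and library size), 1 value for each of 58735 Ensembl genes per library. The submitters' processing notes name BWA, Bowtie and the build hg19, with no roles or versions; the counting tool is not given in the sources used here. The 58735 identifiers all matched GENCODE release 29 (Ensembl release 94, GRCh38). FPKM multiplied by the summed exon length of that release was a whole multiple of 1 step per library for 100% of values above 0 (within 0.05 of a whole number), so whole reads could be recovered; the identifiers and lengths are therefore those of release 29 rather than of an hg19 annotation. Coordinates are given from release 29 on GRCh38. The read totals that the FPKM values imply as divisors, each divided by the geometric mean of the 3 recovered totals, were 1.0446, 0.9629 and 1.0061 (control, knockdown 1, knockdown 2), equal to 4 decimals to median-of-ratios factors computed from the recovered reads. The deposited FPKM values thus already carry such a scaling.

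Assigned reads were 16014485, 16221721 and 16254461. The 10 most abundant genes took 8.83%, 8.09% and 8.50% of reads, mitochondrial genes 6.31%, 6.13% and 6.26%, and protein-coding genes 96.0%, 96.6% and 96.2%. Intervals on single values are exact 95% Poisson intervals of the recovered reads, and floors are set at 3 reads; both cover counting error only.

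The main test, fixed before the data were examined, was limma 3.58.1 in R 4.3.3 with intensity trend on log2(FPKM + 1), for genes with a mean of at least 1 FPKM over the 3 libraries, with Benjamini-Hochberg adjustment at 0.05. Fold changes are on that scale, which understates the change of low genes. The design has 1 residual degree of freedom. The fixed design also named a quasi-likelihood count test for files of counts, which was not used because the files hold FPKM. Genes at least 2-fold apart from the control, in the same direction in both knockdown libraries, were counted without a test. For that count and for the correlation of the fold changes, 100 sets of unchanged libraries were drawn from negative binomial distributions. Each of 30 bins of mean reads had 1 dispersion, taken from the 2 knockdown libraries. Percentiles of a list's median come from 10000 random lists of the same size matched on mean expression (20 bins) and describe these libraries; where stated, lists were matched on expression (10 bins) and gene length (6 bins) among protein-coding genes. Counts for a list are given over all genes tested and adjusted over the list alone. They cover only members with a mean of at least 1 FPKM, for limma-voom as well.

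Named genes followed a rule fixed before the data were examined. It takes TRAF7, TWIST1 and P2RX1, then up to 10 genes per direction past the adjusted threshold and at least 2-fold in both libraries. Since 0 genes passed, the places were filled by genes at least 2-fold in both libraries with a mean of at least 5 FPKM, ranked by the smaller change. Uncharacterised loci, pseudogenes and small RNAs were left out, and names derived from clones were treated in the same way; 3 higher and 6 lower genes met the rule. It then takes up to 4 members with the lowest p of each list. Some genes that the rule takes are not reported here. The 30 lists were fixed at the same time. They cover the TRAF family, nucleotide receptors, calcium handling and calmodulin signalling, TWIST and EMT, NF-kB, immediate early, MEKK3-ERK5-KLF and p53 target genes, and apoptosis regulators. Further lists are G1/S, G2/M, CDK inhibitors, MYC targets, LSC17, stem and progenitor regulators, myeloid differentiation, interferon-stimulated, antigen presentation, unfolded protein response, heat shock, glycolysis, respiratory chain, mitochondrially encoded, cholesterol, ribosomal protein and histone genes. Markers of erythroid, lymphoid, and stromal and epithelial cells complete them. All symbols of the lists were matched, older ones through tables of synonyms.

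Alternatives planned before the data were examined were median-of-ratios rescaling of the tested values, quantile normalization, no filter, a mean of at least 5 FPKM, no intensity trend, pseudocounts of 0.1, 0.5 and 5, and each knockdown library alone. Added after the data were seen were limma-voom on the recovered reads (mean of at least 10 reads), a filter of at least 10 reads, protein-coding genes only, and scaling to all assigned reads.

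Both tests were tested on simulated data in 5 runs with the libraries' own means and dispersion and 200 changed genes per run, for the comparison of 2 knockdown libraries with 1 control. On about 12648 genes, limma on log2(FPKM + 1) called 8.7% of genes changed 2-fold and 71.1% of those changed 4-fold, with 21.8 unchanged genes called per run. On about 15016 genes, limma-voom called 58.4% and 91.5%, with 11.0 unchanged genes called per run. All simulated genes of a mean-read bin had 1 dispersion, a setting that favours tests that pool variance across genes. Genes that vary more than their bin were not modelled, so these rates may not hold in the real libraries. Other steps used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.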

Results

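RNA was sequenced in 3 libraries of cells labelled KG1a, an acute myeloid leukaemia line best known for its CD34 surface antigen. Cells of 1 library, the control, received a lentivirus with a control short hairpin RNA, and cells of 2 libraries a lentivirus with a hairpin against TRAF7, a RING-domain E3 ubiquitin ligase of the TRAF family. The labels number the knockdown libraries 1 and 2 and do not say whether they carry the same hairpin. Reads assigned to genes numbered 16014485 in the control, 16221721 in knockdown 1 and 16254461 in knockdown 2. Genes with a value above 0 numbered 24670, 23269 and 24087. The libraries were separate: the chi-square per gene between the knockdown libraries was 16.76, the same as between the control and knockdown 2, and between the control and knockdown 1 it was 35.49. The series title places TWIST1 and P2RX1 downstream of TRAF7, so the comparison asks how the transcriptome of these cells differs when TRAF7 is depleted.

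TRAF7 transcript was lower in both knockdown libraries, at 33.6% and 39.4% of the control. Its gene (ENSG00000131653, chromosome 16, positions 2155698 to 2178129, plus strand, GRCh38) had 46.5 FPKM in the control (95% Poisson interval 45.0 to 48.1), 15.6 in knockdown 1 (14.7 to 16.6) and 18.3 in knockdown 2 (17.4 to 19.3). These values rest on 3526, 1091 and 1338 reads. The fitted log2 fold change was −1.41 ± 0.19 (SE), with limma's adjusted p = 0.274 over all genes tested. TRAF7 passed among the 6 measured members of the TRAF family adjusted over the list alone (limma adjusted p = 0.00229; lost with no filter on low values), where 0 passed over all genes. TRAF2, TRAF3 and TRAF5 had log2 fold changes of 0.28, 0.11 and 0.11, and the list's median stood at the 57th percentile of expression-matched random lists.

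**Figure D1:**
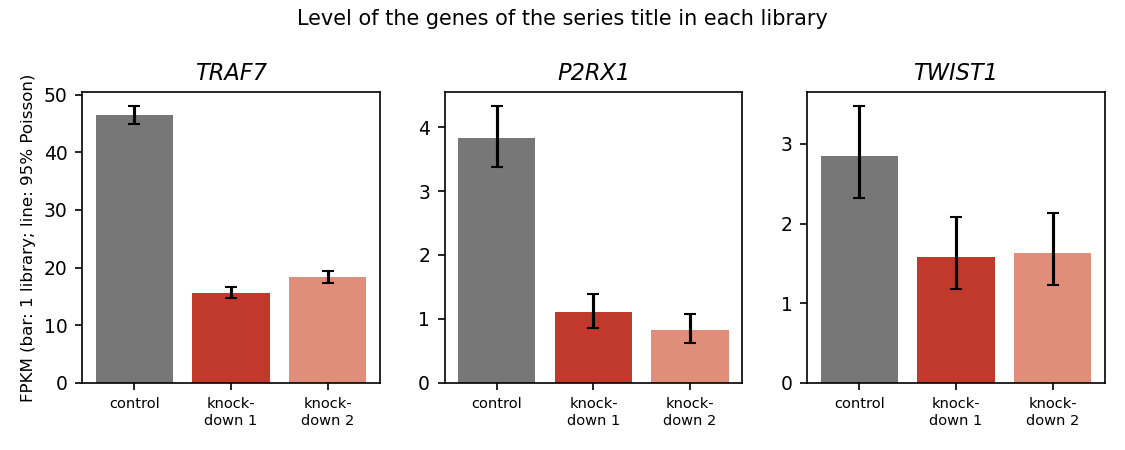
FPKM of TRAF7, P2RX1 and TWIST1 in the control and the 2 knockdown libraries; each bar is 1 library and each line its 95% Poisson interval, which covers counting error only. TRAF7 stood at 46.5 in the control and at 15.6 and 18.3 in the knockdown libraries, and the other genes were also lower in both.

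P2RX1, an ATP-gated cation channel that admits calcium, was lower in both knockdown libraries, at 28.7% and 21.4% of the control. It lies on chromosome 17 at positions 3896592 to 3916500 (minus strand) and had 3.83 FPKM in the control (3.38 to 4.33, 257 reads), 1.10 in knockdown 1 (0.855 to 1.40, 68 reads) and 0.821 in knockdown 2 (0.615 to 1.07, 53 reads). TWIST1, a basic helix-loop-helix transcription factor on chromosome 7 at positions 19020991 to 19117672 (minus strand), had 2.86 FPKM in the control (2.32 to 3.48, 98 reads), 1.58 in knockdown 1 (1.17 to 2.08, 50 reads) and 1.63 in knockdown 2 (1.23 to 2.13, 54 reads). The fitted log2 fold change of P2RX1 was −1.31 ± 0.24 (SE; limma adjusted p = 0.403) and that of TWIST1 was −0.56 ± 0.22 (limma adjusted p = 0.528). Adjusted over the list alone of the 3 genes of the title, limma's p was 0.00114 for TRAF7, 0.00281 for P2RX1 and 0.0413 for TWIST1, and the study may have chosen P2RX1 and TWIST1 on these libraries, so the last 2 are not independent evidence. In limma-voom on reads recovered from the FPKM values, an analysis added after the data were seen, TRAF7 and P2RX1 passed over all genes (adjusted p = 2.69e-05 and 0.000614) and TWIST1 did not (0.406).

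Among the P2X and P2Y nucleotide receptors, P2RX1 alone of 6 measured members passed adjusted over the list alone (limma adjusted p = 0.0112; lost with no filter on low values), and 0 passed over all genes. P2RX6 and P2RX4 had log2 fold changes of −0.42 and −0.30, lower in both libraries, P2RY1 had 0.04, and the list's median stood at the 20th percentile. In the list of calcium entry, stores and pumps, 11 of 23 measured members were lower in both libraries and 6 higher, with 0 passed over all genes and 0 adjusted over the list alone. Its members with the lowest p were ATP2A3, a calcium pump of the endoplasmic reticulum, at 65.7 FPKM in the control and 22.8 and 41.2 in the knockdown libraries, and the store-operated channel genes ORAI3 (log2 fold change −0.62) and ORAI2 (−0.36); ATP2A3 passed by limma-voom over all genes (adjusted p = 0.00452). So did RYR1, a member below the filter of 1 FPKM, at 1.536, 0.6721 and 0.624 FPKM (limma-voom adjusted p = 0.0087). The medians of the measured members were −0.15 in knockdown 1 and −0.02 in knockdown 2, and the fitted median stood at the 0.8th percentile of expression-matched lists. Calcium-calmodulin signalling genes, with 23 measured, had medians of 0.04 and 0.00 (percentile 7.5; 0 passed over all genes and 0 adjusted over the list alone, where 1 fell by limma-voom). CALM3 was at 80.1, 110.3 and 99.2 FPKM, and NFATC4 at 2.05, 0.564 and 1.40, in the order control, knockdown 1, knockdown 2.

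Among characterised genes with a mean of at least 5 FPKM, alpha-globin, a polymerase subunit and a small set of metabolic and signalling genes were at least 2-fold from the control in both knockdown libraries. HBA1 was at 22.9 FPKM in the control and at 90.2 and 74.8 in knockdown 1 and 2, and its neighbour HBA2 at 18.5, 56.2 and 41.9. These genes are near-identical copies on chromosome 16 (positions 176680 to 177522 and 172876 to 173710), so the split of reads between them is uncertain. POLR2L, a subunit shared by the nuclear RNA polymerases (chromosome 11, 837356 to 842545), was at 55.6, 145.0 and 115.0. On the lower side, the calcium-binding protein gene S100P (chromosome 4, 6693069 to 6697170) was at 26.6, 1.91 and 7.83 FPKM, and the mitochondrial folate enzyme gene ALDH1L2 (chromosome 12, 105019784 to 105084577) at 18.8, 3.03 and 6.51. ASS1, which encodes argininosuccinate synthase (chromosome 9, 130444929 to 130501274), was at 21.2, 2.23 and 8.19, and the tetraspanin gene TSPAN32 (chromosome 11, 2301997 to 2318200) at 11.8, 4.90 and 5.25. HIST1H4K, one of many near-identical histone H4 genes (chromosome 6, 27831216 to 27831527), was at 15.2, 7.00 and 6.90. The fitted log2 fold changes were 1.80 ± 0.19 (SE) for HBA1, 1.35 ± 0.22 for HBA2, 1.20 ± 0.19 for POLR2L, −2.45 ± 0.60 for S100P, −1.85 ± 0.37 for ALDH1L2, −2.03 ± 0.57 for ASS1, −1.08 ± 0.17 for TSPAN32 and −1.03 ± 0.17 for HIST1H4K. With TRAF7, these were all the genes that the naming rule gave, 3 higher and 6 lower.

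By limma with trend on log2(FPKM + 1), 0 of 12640 genes tested passed an adjusted p of 0.05; 1161 had an unadjusted p under 0.05, and the smallest adjusted p, 0.206, was that of HBA1. The same test called 3 genes at a mean of at least 5 FPKM (FTL, HBA1 and HSPE1P2, all higher; FTL and HSPE1P2 are outside the naming rule and are named after their values were seen). Among settings added after the data were seen, it called 5 genes at a mean of at least 10 reads and 13 among protein-coding genes, and limma-voom on reads called 130 of 15034 genes, 31 higher and 99 lower, with 1822 at an unadjusted p under 0.05. The single residual degree of freedom comes from the 2 knockdown libraries, and the lone control was assumed to vary as they do. The p-values thus measure the spread between these 2 libraries only, partly pooled across genes. In limma-voom the pooled part had most weight (35.5 prior degrees of freedom against 1 residual).

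By size alone, 98 genes differed at least 2-fold from the control in both knockdown libraries, 43 higher and 55 lower. Knockdown 1 alone held 132 higher and 238 lower, and knockdown 2 alone 87 and 142, so independent lists would share 0.91 and 2.67 genes. Simulated libraries had no change, 1 control shared by both fold changes and redrawn in each set, and the spread of the knockdown pair. They gave a median of 71 such genes (39 higher, 31 lower), and 1 of 100 draws gave 98 or more. By direction, 29 of 100 draws reached the 43 higher genes and 0 reached the 55 lower, where the highest draw gave 52. Of the 98, 59 averaged under 10 reads, a number that 20 of 100 draws reached; the other 39 averaged at least 10 reads, where the highest draw gave 29. The log2 fold changes of the 2 knockdown libraries correlated across the 12640 genes with Pearson r = 0.60, where unchanged libraries gave a median of 0.50; genes are not independent replicates. The covariance was 0.0871 against a simulated 0.0618, a difference of 0.0253. The single control library cannot be split, so part of the excess may come from it. Another part may come from the simulation, which gave all genes of a mean-read bin 1 dispersion. Genes that vary more than their bin, such as EGR1 (9129 and 2320 reads in knockdown 1 and 2), were not modelled. The counts of draws therefore do not measure how rare these numbers are in unchanged libraries.

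**Figure D2:**
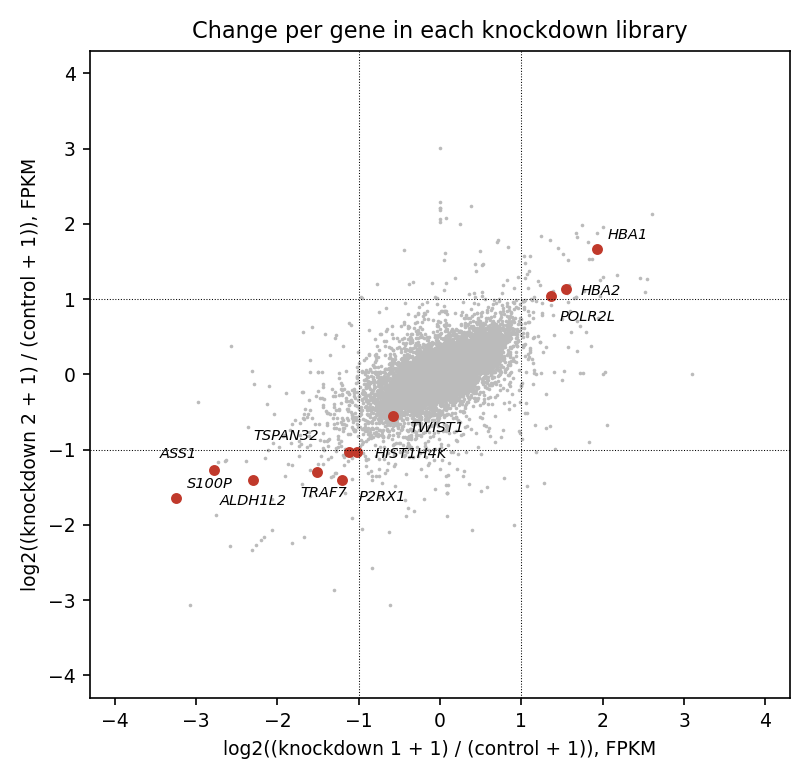
Log2 of (knockdown + 1) over (control + 1), in FPKM, for knockdown 1 (horizontal) and knockdown 2 (vertical); each grey point is 1 tested gene, red points are the genes named by rule, and dotted lines mark 2-fold. The points lie along the diagonal (r = 0.60) with HBA1 and HBA2 at the upper right and S100P, ASS1 and ALDH1L2 at the lower left; both axes share the control library.

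Genes of DNA replication, ribosome biogenesis and protein folding were higher in both knockdown libraries for most measured members of each list. Of 38 measured G1/S and DNA replication genes, 37 were higher in both libraries and 0 lower, with medians of 0.56 in knockdown 1 and 0.38 in knockdown 2 and a fitted median at the 100th percentile of expression-matched random lists. The clamp loader subunit RFC2 was at 25.8, 48.7 and 44.5 FPKM in control, knockdown 1 and knockdown 2, the helicase subunits MCM6 at 33.4, 64.3 and 56.6 and MCM7 at 154.5, 232.8 and 209.0, and the sliding clamp PCNA at 81.1, 143.9 and 125.3. By limma 0 of these passed over all genes and 0 adjusted over the list alone, where the smallest adjusted p was 0.0590; by limma-voom, 2 passed over all genes and 23 adjusted over the list alone. Of 34 G2/M genes, 28 were higher in both and 2 lower (medians 0.26 and 0.31, percentile 99.9; 0 passed over all genes and 0 adjusted over the list alone), among them CCNB1 at 54.8, 86.7 and 79.9 FPKM and CCNA2 at 64.6, 86.4 and 89.0. Of 29 MYC target and ribosome biogenesis genes, 24 were higher in both and 0 lower (medians 0.57 and 0.25, percentile 100). LDHA had a log2 fold change of 0.65 ± 0.13 (SE), HSPE1 of 0.75 ± 0.19, the nucleolar methyltransferase FBL of 0.50 ± 0.13 and NPM1 of 0.40 ± 0.12; 0 passed over all genes and 0 adjusted over the list alone by limma, and 1 and 13 by limma-voom.

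Of 14 heat shock genes, 13 were higher in both libraries and 0 lower, with medians of 0.79 and 0.28 and a percentile of 100. HSPB1 was at 138.9, 260.7 and 210.4 FPKM, HSP90AB1 at 1075, 1584 and 1378, HSP90AA1 at 215.4, 454.1 and 315.6, and HSPE1 at 17.6, 32.5 and 28.3. These 4 chaperone genes rose by limma adjusted over the list alone (adjusted p = 0.0339, 0.0339, 0.0400 and 0.0339), and 0 passed over all genes. The count over the list alone was 0 under median-of-ratios rescaling, quantile normalization, no filter, no intensity trend and scaling to all assigned reads. By limma-voom 2 passed over all genes and 10 adjusted over the list alone.

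Of 27 measured glycolysis and hypoxia genes, 18 were higher in both libraries and 1 lower (medians 0.25 and 0.33, percentile 99.3). The glycolytic enzyme genes ENO1 (421.2, 638.7 and 597.9 FPKM), LDHA (140.1, 222.3 and 217.1), PKM (31.0, 56.9 and 54.0) and PGK1 (log2 fold change 0.66) were among the 7 that rose by limma adjusted over the list alone, and 0 passed over all genes; the count over the list alone fell to 0 under the same 5 settings as for the heat shock genes. By limma-voom 3 rose over all genes, and 9 rose and 1 fell adjusted over the list alone. Of 41 nuclear-encoded respiratory chain genes, 38 were higher in both and 1 lower (medians 0.32 and 0.30, percentile 99.3, or 96.9 when matched on length as well; 0 passed over all genes and 0 adjusted over the list alone, where 2 rose by limma-voom), with UQCRQ at 75.1, 124.7 and 116.4 FPKM and the ATP synthase gene ATP5MC1 at 34.04, 60.5 and 54.2. Mitochondrially encoded genes, with 13 measured, had medians of 0.10 and 0.10 (percentile 8.2; 0 and 0 passed by limma, and 0 and 3 by limma-voom); MT-ND6, MT-ND1 and MT-ND5 had log2 fold changes of 0.64, 0.53 and 0.58. Ribosomal protein genes were higher in both libraries for 39 of 43, but by little (medians 0.10 and 0.14), below most expression-matched lists (percentile 1.2), and with a median of −0.07 under quantile normalization; 0 passed over all genes and 0 adjusted over the list alone.

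The control library held more reads on intronic features than either knockdown library. With 1 control library, any feature that differs there goes with these lists, so a link between them was not tested. The Poisson intervals below did not overlap between the 2 knockdown libraries either, so counting error falls short of the spread between libraries. Reads on the 894 genes annotated as sense intronic came to 553.2 RPM (reads scaled to library size) in the control (95% Poisson interval 541.8 to 564.9), 448.5 in knockdown 1 (438.2 to 458.9) and 475.5 in knockdown 2 (465.0 to 486.2).

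**Figure D3:**
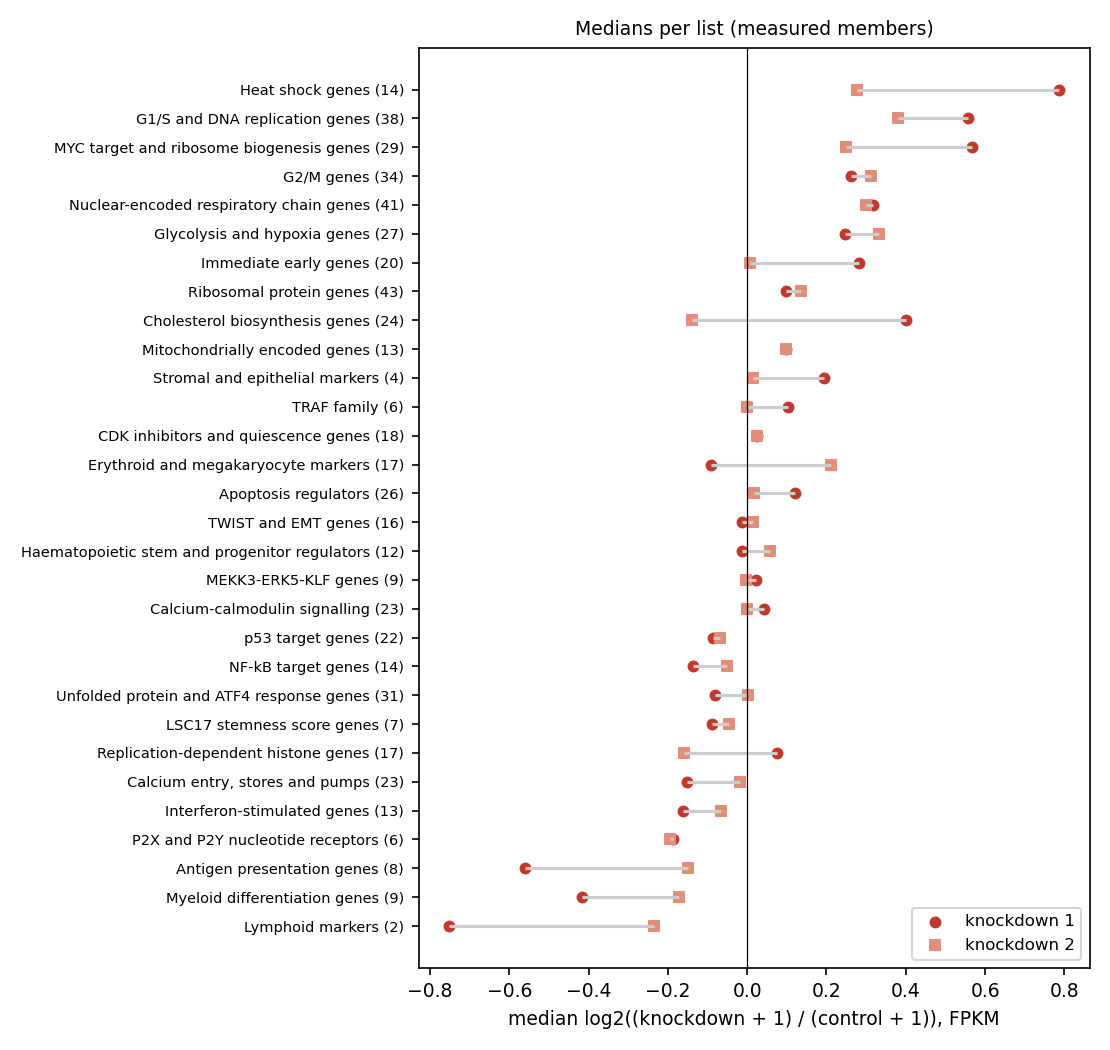
Median log2 of (knockdown + 1) over (control + 1), in FPKM, of the measured members of each gene list in knockdown 1 (circles) and knockdown 2 (squares), with the number of measured members in brackets. Heat shock, DNA replication, MYC target, G2/M and nuclear-encoded respiratory chain lists lie at 0.25 or above in both libraries. Myeloid and antigen presentation lists are among those below 0 in both.

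Most measured myeloid and antigen presentation genes were lower in both knockdown libraries, but most members of these lists were not measured. Of the myeloid list 27 of 36 members fell below the filter, and of the antigen presentation list 15 of 23. Of 9 measured myeloid differentiation genes, 8 were lower in both and 0 higher (medians −0.42 and −0.17, percentile 0.1). The granule protein gene AZU1 was at 5.02, 1.30 and 2.24 FPKM, lysozyme (LYZ) at 8.06, 6.05 and 3.97, and the transcription factor genes CEBPD at 6.36, 4.22 and 4.86 and SPI1 at 5.32, 3.57 and 4.04. By limma, 0 passed over all genes and 0 adjusted over the list alone, where AZU1 had an adjusted p of 0.0527; by limma-voom AZU1 passed over all genes (0.0391). Of 8 antigen presentation genes, 5 were lower in both and 1 higher (medians −0.56 and −0.15, percentile 0.1; 0 and 0 passed), including TAPBP at 19.5, 13.99 and 14.95 FPKM and HLA-E at 31.2, 20.5 and 25.2.

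The list of unfolded protein and ATF4 response genes split. Of 31 measured members, 9 were higher in both libraries and 12 lower, with medians of −0.08 and 0.00 and a percentile of 0.0. PHGDH, the first enzyme of serine synthesis, was at 61.2, 17.98 and 31.6 FPKM and the transcription factor ATF5 at 52.6, 19.5 and 33.3, while the chaperone genes CALR (178.2, 283.9 and 263.4) and SDF2L1 (285.6, 410.1 and 370.2) were higher in both. By limma 0 passed over all genes and 0 adjusted over the list alone. By limma-voom PHGDH and ATF5 fell over all genes (adjusted p = 0.000182 and 0.0120), and 1 rose and 3 fell adjusted over the list alone.

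Among the CDK inhibitors and quiescence genes, cyclin D1 (CCND1), at 8.80, 4.23 and 4.303 FPKM, fell by limma adjusted over the list alone (log2 fold change −0.90 ± 0.17, SE; adjusted p = 0.0423); 0 of 18 passed over all genes, and the call was lost under the 5 settings named for the heat shock genes. CCND1 passed by limma-voom over all genes (0.0106). CDKN1A was at 12.9, 9.31 and 8.69 FPKM, and the list's medians were 0.03 and 0.02 (percentile 34.6). The p53 target list had medians of −0.09 and −0.07 (22 measured, percentile 3.0), with GADD45A at 120.7, 164.6 and 147.4 FPKM. NF-kB target genes had medians of −0.14 and −0.05 (14 measured, percentile 19.1); TNFAIP2 was at 12.7, 5.85 and 7.997 FPKM and NFKBIA at 8.19, 11.7 and 11.7. Immediate early genes had medians of 0.28 and 0.01 (20 measured, percentile 98.9, or 96.2 when matched on length as well), MEKK3-ERK5-KLF genes of 0.02 and 0.00 (9 measured, percentile 47.8), apoptosis regulators of 0.12 and 0.02 (26 measured, percentile 22.6), and TWIST and EMT genes of −0.01 and 0.01 (16 measured, percentile 16.4). In each of these last lists, from p53 targets on, 0 passed by limma over all genes and 0 adjusted over the list alone; TNFAIP2 passed by limma-voom over all genes (0.0356).

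Globin genes stood apart within the erythroid and megakaryocyte markers, of which 17 were measured. HBA1, HBA2, HBG1 (26.4, 58.9 and 53.3 FPKM) and HBZ (65.7, 109.4 and 133.0 FPKM) rose by limma adjusted over the list alone (adjusted p = 0.00165, 0.00649, 0.00649 and 0.0136), and 0 passed over all genes; with no filter on low values 0 passed over the list alone. By limma-voom these 4 and TFRC rose over all genes. HBG1 has a near-identical neighbour, HBG2 (14.6, 16.6 and 17.1 FPKM), so the split of reads between them is uncertain. The list as a whole had medians of −0.09 and 0.21 (percentile 26.0), and the erythroid transcription factor GATA1 was at 128.5, 104.5 and 115.6 FPKM.

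CD34, the antigen for which the labelled line is known, was scarce. It had 0 reads in the control, where the floor of 3 reads is 0.0193 FPKM and the exact upper limit 0.0237, 1 read in knockdown 1 (0.00697 FPKM) and 10 in knockdown 2 (0.0667 FPKM). FLT3, HOXA9 and HLA-DRA had 0 reads in each of the 3 libraries, while the erythroid genes GATA1, KLF1 (56.5, 61.7 and 55.8 FPKM) and NFE2 (57.6, 52.9 and 58.1 FPKM) were expressed in all 3; the genes of this paragraph were chosen after their values were seen.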

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

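The limma-voom, 10-read, protein-coding and total-read settings were chosen after seeing the data. The count of 0 genes past the threshold was also 0 under median-of-ratios rescaling, quantile normalization, no filter, no intensity trend, pseudocounts of 0.1 and 0.5, and scaling to all assigned reads. It was 3 at a mean of at least 5 FPKM (FTL, HBA1 and HSPE1P2), 5 at a mean of at least 10 reads (FTL, HBA1, HSPE1P2 and the clone-named AC117500.3 and AC117500.5), 13 among protein-coding genes and 130 with limma-voom. These settings test other sets of genes and pool variance across genes to other degrees. The prior degrees of freedom, the weight of the pooled variance, were 4.742 or fewer in each setting with 0 calls. They were 9.274 at a mean of at least 5 FPKM, 7.974 at 10 reads, 11.54 among protein-coding genes and 35.5 with limma-voom. What else moved the counts was not tested. TRAF7 passed with limma-voom (log2 fold change −1.46) and among protein-coding genes (−1.41), and so did P2RX1 (−2.01 and −1.31). TRAF7, P2RX1 and TWIST1 were below the control in every setting that tested them; a mean of at least 5 FPKM left P2RX1 and TWIST1 untested. Adjusted p of TRAF7 ran from 2.69e-05 to 0.649 over the settings, of P2RX1 from 0.000614 to 0.649, and of TWIST1 from 0.261 to 0.649. Leaving out knockdown replicate 1 or 2 leaves no residual degree of freedom, so only values can be given: −1.52 to −1.30 for TRAF7, −1.41 to −1.20 for P2RX1 and −0.58 to −0.55 for TWIST1.

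The count of 98 genes at least 2-fold in both libraries was 236 with a pseudocount of 0.1, 7 with a pseudocount of 5, 185 with no filter, 19 at a mean of at least 5 FPKM, 39 at a mean of at least 10 reads and 16 among protein-coding genes; with 1 knockdown library alone it was 229 to 370. Pseudocount and filter act on genes with few reads, which made up 59 of the 98. The split between higher and lower was 43 and 55 as deposited, 37 and 62 after median-of-ratios rescaling, 54 and 49 after quantile normalization, and 33 and 76 with total-read scaling. The correlation of 0.60 was 0.54 and 0.66 with pseudocounts of 0.1 and 5 and 0.65 at a mean of at least 5 FPKM; the cause was not tested. Small values changed sign for P2RY1 (−0.005 after median-of-ratios rescaling, −0.049 with total-read scaling), RPL8 (−0.047) and EPCAM (−0.008) after quantile normalization, and KRT18 (−0.14 after quantile normalization, −0.01 with total-read scaling); the cause was not tested. Medians of lists changed sign at a mean of at least 5 FPKM for interferon-stimulated (−0.12 to 0.23), MEKK3-ERK5-KLF (−0.03 to 0.18) and calcium-calmodulin genes (−0.04 to 0.08), and with no filter for lymphoid markers (−0.49 to 0.01). They changed sign after quantile normalization for ribosomal protein (0.13 to −0.07), stromal and epithelial (0.10 to −0.07) and CDK inhibitor genes (0.06 to −0.08). The TRAF, TWIST and EMT, apoptosis, stem and progenitor, and erythroid lists, with medians within 0.1 of 0, also changed sign under at least 1 setting. Count models for deposited counts were not run because the files hold FPKM. No paired analysis was possible because the control carries no replicate number.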

Other observations

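Cholesterol biosynthesis and histone genes had medians of opposite sign in the 2 knockdown libraries, a difference that was not tested. Cholesterol biosynthesis genes had a median of 0.40 in knockdown 1 and −0.14 in knockdown 2 (24 measured, percentile 54.3), with 3 members higher in both libraries and 4 lower; EBP was at 25.4, 41.3 and 31.0 FPKM in control, knockdown 1 and knockdown 2, and SREBF2 at 44.1, 37.3 and 34.5. Replication-dependent histone genes had medians of 0.08 and −0.16 (17 measured, percentile 0.2), with HIST1H2AG at 41.4, 27.2 and 24.6 FPKM. Interferon-stimulated genes had medians of −0.16 and −0.07 (13 measured, percentile 5.9; the fitted median of −0.12 was 0.23 at a mean of at least 5 FPKM), with BST2 at 97.3, 133.9 and 124.2 FPKM. LSC17 stemness score genes had medians of −0.09 and −0.05 (7 measured, percentile 5.2), and stem and progenitor regulators of −0.01 and 0.06 (12 measured, percentile 16.2), with GATA2 at 40.5, 45.3 and 48.8 FPKM. Lymphoid markers had 2 measured members (medians −0.75 and −0.24, percentile 3.6) and stromal and epithelial markers 4 (medians 0.19 and 0.01, percentile 26.4). By limma, 0 members of these lists passed over all genes and 0 adjusted over the list alone, where 1 histone gene fell by limma-voom. The interferon-stimulated gene OAS3, below the filter of 1 FPKM, fell by limma-voom over all genes (1.235, 0.2414 and 0.4099 FPKM, adjusted p = 0.005594).

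In the weighing that follows, the tests on length and abundance, on CD34, on HBZ and on erythroid markers other than globins were chosen after their results had been seen in part, and the other tests on olfactory, sense intronic and chromosome 16 genes were written before. Genomic background and unspliced RNA were made separate explanations only after the olfactory sum was seen to rest mostly on OR51B5.

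The DNA replication, MYC target and heat shock lists, together 79 protein-coding genes with a median log2 fold change of 0.45, were higher in both knockdown libraries (medians 0.57 and 0.31). A trend with abundance and gene length is argued against as the whole cause. Matched random lists had a median of 0.17, and the lists stood at their 100th percentile. The top 3 of 30 matched random lists reached 0.45 in 6 of 10000 sets. Random genes were drawn independently, whereas members of a real list may vary together. That count is therefore not a p-value for unchanged libraries. More unspliced RNA in the control library stays open, since reads on sense intronic genes were 553.2 RPM there against 448.5 and 475.5. That gap would be smaller with the divisors of the FPKM values. Genomic background cannot be told apart, because olfactory receptor reads (240.2 RPM in the control, 231.1 and 234.7 in the knockdown libraries) lay within the interval of knockdown 2 (up to 242.3), the bound set against it, but came mostly from 1 gene, OR51B5 (62.9% in the control), and outside chromosome 11 were 14.8, 13.4 and 12.2 RPM with overlapping intervals. An effect of TRAF7 depletion also stays open, and with 1 control library neither it nor the state of that library can be separated from the rest.

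The libraries labelled KG1a held almost no CD34 and expressed erythroid genes. A cell line other than KG1a, or a culture that no longer carries CD34, may account for this: the highest CD34 value of the 3 libraries was 0.0667 FPKM, while GATA1 stood at 104.5 to 128.5 FPKM. Erythroid cells mixed into KG1a cells would leave the CD34 of the KG1a part; the control had 0 reads (0.0193 FPKM at the floor of 3 reads, exact upper limit 0.0237), but 1 gene near its floor cannot exclude a mixture, so this stays open. No biological explanation was tested, since the 3 libraries share it.

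The globin genes on chromosome 16 were higher in both knockdown libraries. A change of the whole end of the chromosome is argued against for HBA1 and HBA2: the 12 other protein-coding genes tested within its first 500 kb had a median log2 fold change of 0.22, at the 87.6th percentile of lists matched on expression and length, against 1.80 for HBA1 and 1.35 for HBA2. For HBZ (0.87) a change shared with neighbours cannot be told apart, since 10 of the 12 were above 0, up to 0.86 for SNRNP25. A higher level of the erythroid programme as a whole is argued against as well, since the 11 measured markers other than globins had a median of −0.20, at the 0.4th percentile, with TFRC (49.5, 95.7 and 72.0 FPKM) an exception. A change limited to globin transcripts in response to TRAF7 depletion stays open as a hypothesis that was not tested here, as does the state of the single control library.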
